A study of Gallus gallus with 4 samples.

How the data were processed

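Whole-genome bisulfite libraries were made by adaptor tagging after bisulfite treatment from tissue around beads soaked in 5-azacytidine or DMSO, with 2 libraries per group. The submitters' processing notes name Trim Galore, fastp, Bismark, MethylDackel and methylKit, and the genome build GRCg6a, without versions or an order of steps. Removal of duplicate reads and filters on calls are not given in the sources used here. Per the file headers, the deposited tables list each CpG cytosine on each strand with its coverage as a count of calls. Per the file headers, the deposited tables also give the percent of those calls read as C (methylated) and as T (unmethylated). Methylated counts were obtained by multiplying coverage by the percent and rounding, and both percents added up to 100 in every row. Whole numbers within 0.1 came out for 99.9978% of rows in 5-azacytidine replicate 2 and for a higher share in the other libraries.

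The methylation level of a set of cytosines is the share of methylated calls among all calls. Cytosines above the 99.9th coverage percentile of their library (limits of 50 and 44 calls for DMSO, 48 and 60 for 5-azacytidine) were left out, which removed 4.44, 4.89, 5.06 and 11.3% of calls in DMSO replicates 1 and 2 and 5-azacytidine replicates 1 and 2. Windows of 1000 bp were tested with at least 3 cytosines and 20 calls in every library, and single cytosines with at least 10 calls in every library. The mitochondrion was kept out of windows, tests of single cytosines and chromosome values. Bisulfite reads without molecular identifiers are not independent molecules. The intervals of library levels treat calls as independent, so they are likely too narrow even for counting error, and they leave out the spread between libraries.

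Levels were compared with an exact two-sided permutation test of the library values, which cannot go below 0.333 with 2 against 2. Windows and cytosines were compared with a quasi-binomial logistic model, with a Pearson dispersion per feature shrunk towards a common value by limma's squeezeVar, kept at 1 or above, and Benjamini-Hochberg adjustment at 0.05. The common dispersion of windows was 1.83. It carried 109.9 prior degrees of freedom against 2 from the window itself, so a window's own spread counted little. For single cytosines the prior degrees of freedom were infinite, so every cytosine was given the same dispersion of 1.498. Nothing in the labels says that the libraries of a group came from separate embryos. The depth of chromosomes W and Z, given under the other observations, argues against repeats of one tissue sample. How many embryos each library holds is not known. The p-values rest on the spread between these libraries, mostly shared over features, and part of it may be technical. The labels give no batch.

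The tests were checked on simulated data with the real depths, with a dispersion of 1.8 for windows and of 1 and 1.498 for cytosines, the last estimated from the real ones and added after the data were examined. Changes were placed only in features with an intermediate pooled level, so recovery at other levels is not known. Of windows changed by 10, 20, 30 and 40 points, 50 each among 153328 windows, the main test recovered 2, 20, 40 and 70%. It called 4 unchanged windows. edgeR recovered 0, 16, 32 and 64%, and limma on unweighted log2 ratios, with 0.5 added to each count, recovered 0% at every size. A first form of the main test, with the shrinkage estimated from all features, recovered 0% of changed cytosines at every size and 2, 20, 40 and 70% of changed windows. The shrinkage was then estimated only from features with a binomial variance of at least 1 in every library. This change was made after results on the real libraries had been seen. The main counts of 11 windows and 0 cytosines were the same before and after it, but cytosines called without the upper coverage limit went from 0 to 431.

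Tests, windows, minimums and the main alternatives were set before the data were examined. Named windows are the 5 with the largest rise and the 5 with the largest fall among called windows with the same sign in all 4 pairs of one treated and one control library. Classes of CpG density and methylation level, bins of 100 kb and 1 Mb, unmethylated domains (at least 5 adjacent windows with a pooled level under 15%) and the standardisation to one density make-up were added after the data were examined. Level classes were first formed and read on all calls, which gave 0.31 points in the highest class, with overlapping groups. They were then formed by classing a window on one strand and reading its level on the other, after that first outcome had been seen. Alternatives covered the coverage limits, the minimum calls, window sizes, the test, thinning to the shallowest library, and leaving out each library.

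Promoters, gene bodies, CpG islands, feature classes and gene lists were planned, and were not run because no annotation or sequence of GRCg6a was used here. The gene table at hand describes another build, so no gene is given for any position. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16.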

Results

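CpG methylation was measured by whole-genome bisulfite sequencing in chick embryo hindlimb tissue taken from immediately around beads implanted in the third interdigit, the soft tissue between digits that is normally removed as the digits separate. Embryos were at Hamburger-Hamilton stage 28. The beads had been soaked either in 250 micromolar 5-azacytidine, a cytidine analogue that is built into nucleic acids and traps DNA methyltransferases, or in 50% DMSO, the solvent control, and the tissue was collected after 4 hours. Each group had 2 libraries. The comparison asks whether local exposure to a methyltransferase inhibitor changed DNA methylation in this tissue.

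The DMSO libraries held 31279983 and 37592616 calls on CpG cytosines, and the 5-azacytidine libraries 18719125 and 41899980. A cytosine with any call had on average 3.12 and 3.28 calls in the DMSO libraries and 2.64 and 3.91 calls in the 5-azacytidine libraries. Across the 4 libraries 16047170 cytosines of both strands were seen, and 59502 of them had at least 10 calls in every library, so single cytosines were measured coarsely and most statements below rest on calls summed over windows, chromosomes or the genome.

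Genome-wide CpG methylation was slightly lower around the 5-azacytidine beads. The level was 50.86% ± 0.067 (SD, n = 2) with DMSO and 49.82% ± 0.028 (SD, n = 2) with 5-azacytidine, a difference of -1.04 percentage points. Both 5-azacytidine libraries, at 49.84% and 49.80%, lay below both DMSO libraries, at 50.81% and 50.91%. The 95% Wilson interval of each library's level was narrow, for example 49.81 to 49.86% in 5-azacytidine replicate 1. It treats calls as independent, so it is likely too narrow even for counting error, and it leaves out the spread between libraries. An exact two-sided permutation test gave p = 0.333, the smallest p that 2 libraries against 2 allow. The size and, in one setting, the direction depended on which cytosines were counted. The difference was -0.53 points when every library was given one CpG density make-up. Both 5-azacytidine libraries, at 49.86 and 50.27%, were still below the DMSO libraries, at 50.86 and 50.33%. Replicate 2 of each group lay close together there. The groups overlapped in further settings. As the mean of levels of cytosines with 5 calls the difference was -0.89 points, carried by 5-azacytidine replicate 2 at 47.02%. There 5-azacytidine replicate 1, at 48.73%, lay between the DMSO libraries at 48.72 and 48.81%. Over all calls of the tested 1 kb windows the difference was -0.42 points. It was -0.13 points over cytosines with at least 5 calls in all 4 libraries. Over cytosines with at least 10 it was 0.54 points, higher with 5-azacytidine. Without the upper coverage limit it was -2.55 points, and -1.05 points when a block of chromosome 16 with many calls in 5-azacytidine replicate 2 was also left out.

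The lower level was seen along most chromosomes. On 30 of 34 chromosomes both 5-azacytidine libraries lay below both DMSO libraries, an arrangement that chance gives in 16.7% of cases for one chromosome. Chromosomes are not independent, since the same 4 libraries give each value. On the 29 of them other than chromosome 16 the difference lay between -0.61 and -1.70 points, and on chromosomes 1 to 10 between -1.21 and -1.70 points. On chromosome 7 the level went from 48.54% ± 0.48 (SD, n = 2) with DMSO to 46.84% ± 0.026 (SD, n = 2), and on the Z chromosome from 50.60% ± 0.45 to 49.07% ± 0.16. Chromosome 16 had the lowest difference, -4.51 points, with a wide spread between libraries (57.5% ± 1.5 with DMSO and 53.0% ± 2.7 with 5-azacytidine). Replicates 1 and 2 were at 56.4 and 58.6% with DMSO and at 51.1 and 54.9% with 5-azacytidine, so its size leaned on 5-azacytidine replicate 1. Chromosome 16 also holds a block of low methylation in which the coverage limit, set per library, could keep different cytosines. One 1 kb window there, from 1839001, had levels of 11.3 to 24.1%. It kept 2147 calls in 5-azacytidine replicate 1 and 1045 in replicate 2, against 915 and 444 with DMSO. How much of the -4.51 points came from such unequal weights was not tested. The difference was -2.76 points on that chromosome after removing the part set by CpG density. It was 0.15 points, with overlapping groups, over cytosines with at least 5 calls in all 4 libraries. The groups overlapped on chromosomes 14, 31, 33 and W, and chromosome 33 was 0.96 points higher with 5-azacytidine. Exact permutation p was 0.333 for each separated chromosome, the smallest possible. Over cytosines with at least 5 calls in all 4 libraries, 19 chromosomes were separated in this direction.

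**Figure D1:**
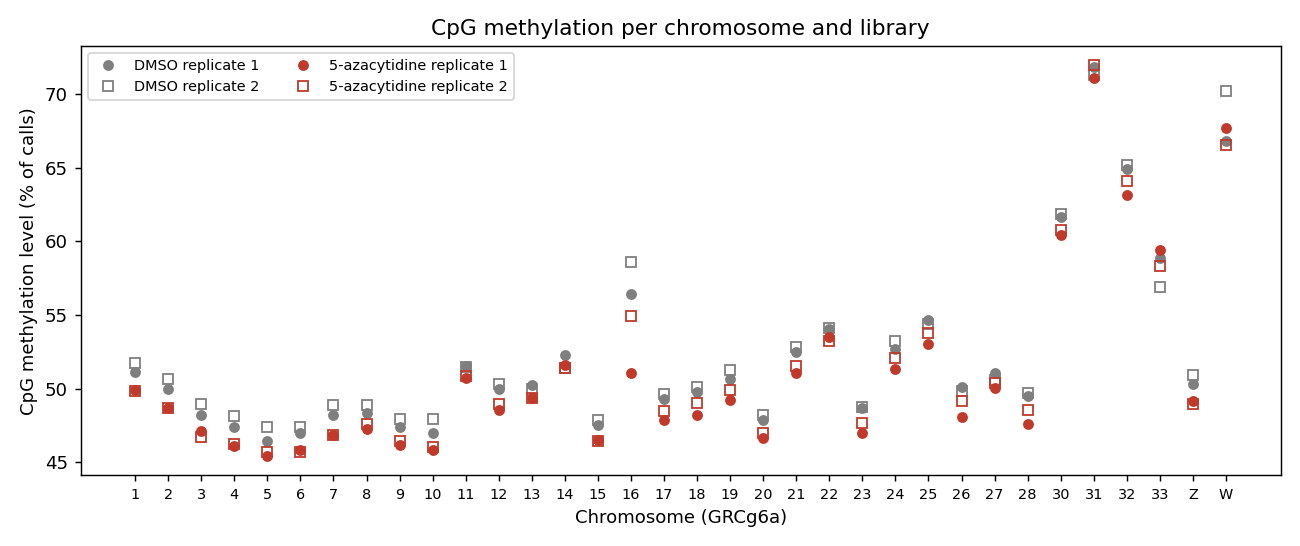
CpG methylation level in percent of calls (vertical axis, not starting at 0) on each chromosome of GRCg6a (horizontal axis), one point per library, with DMSO in grey and 5-azacytidine in red, circles for replicate 1 and squares for replicate 2. Both red points lie below both grey points on 30 of 34 chromosomes, and chromosomes 14, 31, 33 and W are the exceptions.

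The difference was seen in windows with fewer CpGs, and the groups overlapped in the windows richest in CpG. In windows of 1 kb with 1 to 9 cytosines the level was 69.7% ± 0.26 with DMSO and 68.9% ± 0.43 with 5-azacytidine, and in windows with 40 to 79 cytosines it was 58.4% ± 0.11 and 57.3% ± 0.61 (SD, n = 2 each). In the 4 classes below 80 cytosines the differences were -0.76, -0.82, -0.98 and -1.14 points, and both 5-azacytidine libraries were below both DMSO libraries. Without 5-azacytidine replicate 1 these differences were -0.45, -0.43, -0.63 and -0.71 points. In windows with 80 to 119 cytosines the difference was -0.62 points and the groups overlapped, with 0.04 points without DMSO replicate 1, -1.27 without DMSO replicate 2 and -0.35 without 5-azacytidine replicate 1. In windows with 120 or more cytosines, which had the lowest methylation, the level was 23.6% ± 1.3 with DMSO and 24.0% ± 0.46 with 5-azacytidine, and the groups overlapped. That difference of 0.48 points was 1.40 without DMSO replicate 1, -0.43 without DMSO replicate 2, 0.16 without 5-azacytidine replicate 1 and 0.81 without 5-azacytidine replicate 2. Exact permutation p was 0.333 at best for each class. These classes were formed after the data were examined.

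**Figure D2:**
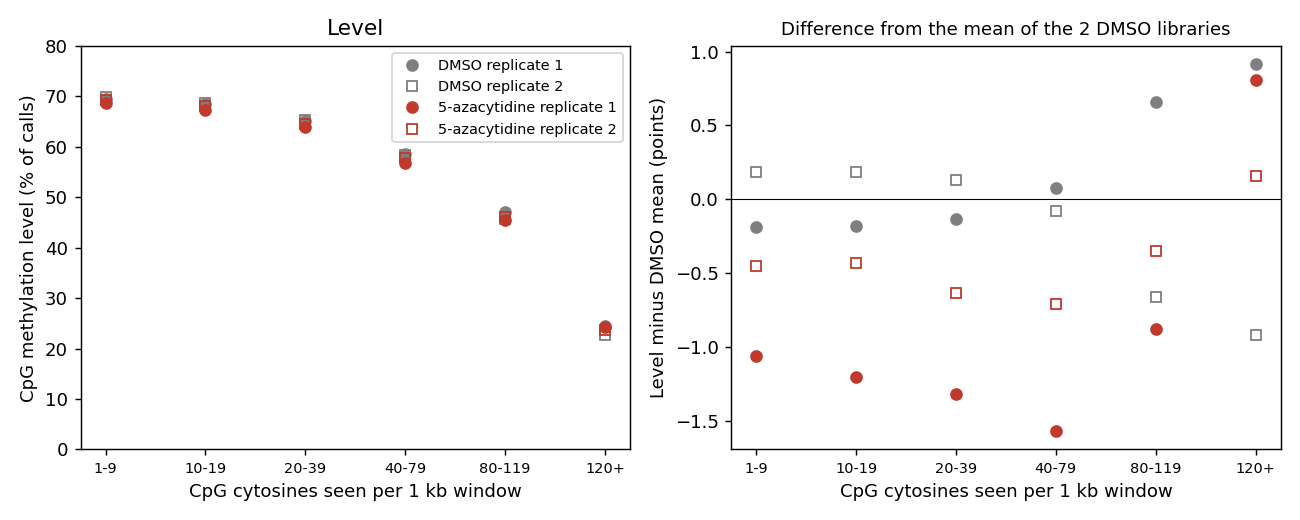
Left, CpG methylation level in percent of calls by the number of CpG cytosines seen per 1 kb window, one point per library. Right, the same levels minus the mean of the 2 DMSO libraries, in percentage points, with DMSO in grey and 5-azacytidine in red. The red points lie below the grey points in the 4 classes below 80 cytosines and overlap with them in the others.

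Along the genome the difference was broad. Of 1086 bins of 1 Mb with at least 1000 calls in every library, 768 (70.7%) were lower in both 5-azacytidine libraries than in both DMSO libraries and 3 were higher. The median difference was -1.53 points. When the same 4 libraries were split by replicate number or crosswise, the largest share of bins on one side was 12.6%. A bin separated in the real split cannot be separated in another, so these splits are no independent control. Bins are not independent of each other either, since the same 4 libraries give each value. No 1 Mb bin passed the moderated quasi-binomial test after Benjamini-Hochberg adjustment, although 415 bins had an unadjusted p under 0.05. The split by replicate number had 15 such bins and the crosswise split 12, and after adjustment they called 3 and 0 bins. In those splits the difference between 5-azacytidine and DMSO enters the residual spread and lowers the number of small p, so they do not measure chance. The bins were chosen after the data were examined.

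**Figure D3:**
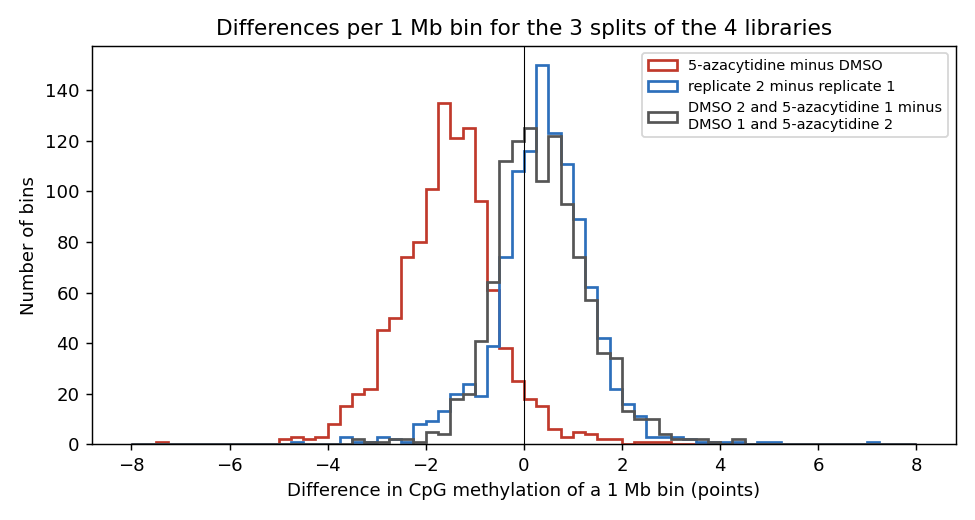
Distribution of the difference in CpG methylation per 1 Mb bin, in percentage points, for the 3 ways to split the 4 libraries into pairs, with the number of bins on the vertical axis. The red outline, 5-azacytidine minus DMSO, has a median of -1.53 points, and the outlines of the other splits have medians of 0.40 and 0.30 points.

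Few single regions were called. The test sets a window against a spread shared almost wholly across windows, so a called difference need not exceed that window's own spread. Of 153328 windows of 1 kb tested, with a median of 76 calls per library, 11 passed the moderated quasi-binomial test at an adjusted p under 0.05, 10 lower and 1 higher with 5-azacytidine. The split by replicate number called 14 windows and the crosswise split 6. The crosswise split sets DMSO replicate 2 and 5-azacytidine replicate 1 against the other libraries. Their depth of chromosome W relative to autosomes was 0.488 and 0.541, against 0.353 and 0.331, and that of Z was lower. Its calls may therefore include differences in sex make-up, which was not tested. In windows of 5000 bp the counts were 18 for the real split (15 lower), 6 by replicate number and 0 crosswise. In the same order they were 11, 16 and 5 in windows of 500 bp, and 1, 0 and 1 in windows of 100 kb. The 100 kb window called in the real split, from 1800001 on chromosome 16, includes the block with extra calls in 5-azacytidine replicate 2. Neither edgeR nor limma called any window. In simulated data edgeR recovered 0, 16, 32 and 64% of windows changed by 10, 20, 30 and 40 points. The main test recovered 2, 20, 40 and 70%, and limma 0% at every size. The 0 calls of limma thus say little about the 11 windows. Those of edgeR count against them, by an amount that the simulation does not set. All simulated windows shared one dispersion, and the 11 windows had more calls than the median. Most changes of 10 points would be missed by each of these tests. Positions are in GRCg6a, and the genes at these positions were not analysed here.

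The window at chromosome 8, 25600001 to 25601000, with 133 cytosines and 458 to 1020 calls per library, had a level of 55.7% ± 2.0 with DMSO and 38.0% ± 4.0 with 5-azacytidine (SD, n = 2), a difference of -17.7 points (moderated quasi-binomial test with limma's shrinkage, adjusted p = 0.000206). It was the only window of the 11 that stayed past the threshold without any one of the 4 libraries. The lowest difference was at chromosome 9, 3785001 to 3786000, where the level was 68.4% ± 1.4 with DMSO and 42.1% ± 1.8 with 5-azacytidine over 120 to 205 calls per library. At chromosome 26, 5501001 to 5502000, the level was 60.3% ± 8.2 and 39.1% ± 0.46. At chromosome 20, 4692001 to 4693000, it was 55.0% ± 5.1 and 38.2% ± 1.4, a difference of -16.8 points that was -3.46 points without the upper coverage limit, where the call was lost (quasi-binomial test with limma's shrinkage, adjusted p = 0.995, and 1.61e-08 to 0.9999 over all alternatives). At chromosome 17, 8591001 to 8592000, it was 72.8% ± 4.2 and 58.8% ± 5.6, and the pooled difference of -15.3 points was -10.2 points without 5-azacytidine replicate 2. The only window that was higher lay at chromosome 9, 23518001 to 23519000, with 20.6% ± 2.6 under DMSO and 36.1% ± 3.9 under 5-azacytidine. Each of these 5 windows lost the call without at least 2 of the 4 libraries in turn, and without 5-azacytidine replicate 2 only 1 of the 11 windows was called again.

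The remaining 5 called windows fell outside the naming rule and are named because they complete the count. The windows starting at 6265001 on chromosome 33 and at 91259001 on chromosome 4 differed by -14.0 and -9.87 points. Those starting at 1803001, 1839001 and 1841001 on chromosome 16 differed by -12.7, -9.63 and -6.64 points. The last 2 of them lie in the block where 5-azacytidine replicate 2 had extra calls. There the coverage limit, set per library, could keep different cytosines in each library. The window at 1839001 kept 915 and 444 calls in DMSO replicates 1 and 2, and 2147 and 1045 in 5-azacytidine replicates 1 and 2. Over all calls of the block without the limit, 5-azacytidine replicate 1 was at 11.5%, between the DMSO libraries at 8.81 and 12.1%. Without the limit 9 of the 11 windows were called again and all 11 kept their direction. In the block that setting also counts the extra calls of 5-azacytidine replicate 2. It therefore cannot tell whether the limit gave these 2 called windows. In the window at 1803001 the groups overlapped, and the difference was -2.2 points without 5-azacytidine replicate 2, -4.8 without DMSO replicate 2, -20.6 without DMSO replicate 1 and -23.1 without 5-azacytidine replicate 1. In the window on chromosome 33 it was -9.0 points without DMSO replicate 2.

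**Figure D4:**
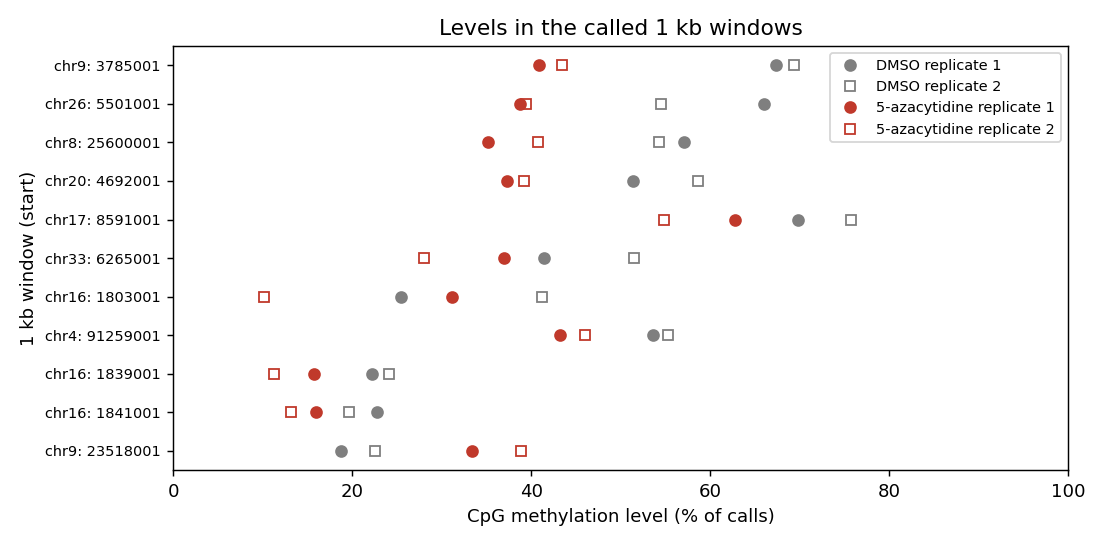
CpG methylation level in percent of calls (horizontal axis) in the 11 called 1 kb windows, one point per library, DMSO in grey and 5-azacytidine in red. The red points lie left of the grey points in 9 windows, right of them in 1 window on chromosome 9, and among them in the window at 1803001 on chromosome 16.

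No single cytosine passed the test. Of 59458 cytosines outside the mitochondrion with at least 10 calls in every library, the moderated quasi-binomial test called 0, with 3036 at an unadjusted p under 0.05. Limma also called 0, but it recovered 0% of changed cytosines in simulated data. Fisher's exact test on pooled calls called 2, and the binomial model without extra spread called 11. In simulated data with a dispersion of 1.498 that binomial model called 61 unchanged cytosines. In simulated data with the depth and the dispersion of these cytosines (1.498) the moderated quasi-binomial test recovered 10% of cytosines changed by 40 points. It recovered 0% of those changed by 30 points or less. The changed cytosines all had an intermediate pooled level, so most changes of these sizes were not detectable at such cytosines. Other levels were not simulated.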

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

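All tests of explanations in this part were chosen after the results were seen. Their bounds were also changed after their values had been seen, from 2 standard errors to a 95% interval with 2 degrees of freedom (a multiplier of 4.30), which left more explanations open.

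A block of chromosome 16 from 1838001 to 1843000 took 7.81% of all calls in 5-azacytidine replicate 2, against 0.97 and 1.41% in the DMSO libraries and 0.69% in 5-azacytidine replicate 1. Calls at cytosines above the coverage limit were left out of the main measurement, but the other calls of the block were in it. The limit was set per library, so it could leave different cytosines in each. Without the limit all 11 called windows kept their direction and 9 were called again, but the extra calls then enter the block. That setting cannot tell whether the limit gave the 2 called windows that lie there. The level there was 2.93% in 5-azacytidine replicate 2 and 8.81 to 12.1% in the other libraries. More copies of the same DNA at an unchanged level would carry the level of the other libraries. The extra calls had a mean level of 1.97% (1.85 to 2.16% against each other library). The lowest level of the other libraries at the same cytosines was 6.68%, which argues against copies at an unchanged level. Copies with a level below the mean of the block are not covered by this comparison. The excess was patchy along the block, with a spread over cytosines 3.03 times the largest spread between other libraries, which reads from another organism with similar sequence would give. Duplicates of a limited set of fragments, which need not carry the mean level, would also give it and stay open, and what the block is was not established.

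The lower methylation in both 5-azacytidine libraries was weighed against technical explanations. If less unconverted cytosine, spread evenly over the genome, were the cause, unmethylated domains would have to be lower by 2.13 points. Their difference was -0.12 points, with an interval from -0.58 to 0.33, which argues against an even change as the whole cause. An uneven one is not excluded, since the domains cover a part of the genome chosen by its low level in these libraries. Methylated cytosines read as unmethylated would cost every window the same share of its level. Windows at 80 to 100% lost a smaller share than windows at 40 to 60%, by 1.38 percentage points of relative level, but the interval from -0.32 to 3.08 includes 0 and leaves this open. Different CpG density of the covered windows also stays open: the smallest fall within a density class below 80 cytosines was -0.76 points with an interval from -2.29 to 0.77, and one density make-up moved the genome-wide difference to -0.53 points, mostly through DMSO replicate 2 and 5-azacytidine replicate 2. After the part set by density was removed, both 5-azacytidine libraries were still lower on 27 of 34 chromosomes (30 before). They were also lower in 63.9% of 1 Mb bins (70.7% before). Another split reached at most 16.4%, but the splits compete for the same bins. The median level of the bins differed by -1.15 points, but with an interval from -2.59 to 0.29 that includes 0. An effect of 5-azacytidine is the explanation that the design names, and an unlabelled difference in preparation would look alike.

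Of the 3 splits of the 4 libraries, 2 called at least 11 windows, the real one with 11 and the highest other with 14. In windows of 5000 bp the real split called 18 and the highest other 6. In windows of 500 bp they called 11 and 16, and in windows of 100 kb 1 and 1. For 1 Mb bins, 1 split, the real one, reached 70.7% on one side, and the highest other reached 12.6%. A bin separated in the real split cannot be separated in another, so a high share there forces low shares in the others. With 3 splits no share under 0.05 is possible. The crosswise split also divides the libraries by their depth of chromosomes W and Z, so it is no neutral control.

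Single cytosines on chromosomes 1 and 5 had 17185 and 19374 calls in 5-azacytidine replicate 1 at most 3 in either DMSO library, and 7 and 0 in 5-azacytidine replicate 2, so these are pileups in one library. The mitochondrial share of all calls was 0.758 and 0.548% in 5-azacytidine replicates 1 and 2, above the 0.458 and 0.485% of the DMSO libraries.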

How the results depend on the processing

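The alternatives with density standardisation, autosomes, tested windows, equal weights for cytosines covered in all libraries, thinned global levels, shrinkage from all features, classes from all calls, the chromosome 16 block, bins of 100 kb and windows of 100 kb and 1 Mb were added after the data were examined. The genome-wide difference of -1.04 points was -1.09 to -0.997 without one library, and moved by less than the spread between libraries after thinning and without the upper coverage limit once the chromosome 16 block was removed. It was -2.55 points with no upper limit, -1.27 on autosomes, -0.62 as the mean of levels of tested windows and -0.53 with one density make-up. The groups overlapped at -0.89 as the mean of levels of cytosines with 5 calls, a value carried by 5-azacytidine replicate 2. They also overlapped, with a difference of -0.42 over all calls of tested windows and -0.13 over cytosines with 5 calls in all libraries. The genome-wide difference reversed to 0.54 points, again with overlap, over calls of cytosines with 10 calls in all libraries, and the cause was not tested. With each of these cytosines weighted equally it was -0.039 (overlap) for 10 calls and -0.21 (separated) for 5. Separated chromosomes numbered 30, 27 after removing the part set by CpG density, 19 over cytosines with 5 calls in all libraries and 31 to 32 without one library. The share of lower bins was 70.7% at 1 Mb, 63.9% after removing the density part, 43.0% at 100 kb and 74.9 to 89.0% without one library, where fewer libraries have to agree.

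The count of 11 windows depended on the setting. It was 44 with no upper limit, 38 and 2 with minimums of 10 and 50 calls, 1 after thinning, 1 with a difference of at least 25 points, 18 in windows of 5000 bp, 1 in windows of 100 kb and 0 in windows of 1 Mb. It was 2794 in a binomial model with no extra spread, 0 in edgeR and 0 in limma with or without median centring. In simulated data that binomial model called 1504 unchanged windows, so its count is inflated. Without one library it was 11 to 22, and 5, 4, 7 and 1 of the 11 windows were called again without DMSO replicates 1 and 2 and 5-azacytidine replicates 1 and 2. All 11 kept their direction in these fits. The 6 named windows had 13 alternatives each, of which 35 of 78 kept the call, 43 lost it and none turned direction. The count of 0 cytosines became 11 in the binomial model, 2 in Fisher's exact test and 431 with no upper limit, 420 of these in the chromosome 16 block; it stayed at 0 otherwise. Deviations of same-numbered libraries from their group means were not correlated across windows (r = -0.00036). This cannot exclude a shared preparation, since counting error is large in single windows and r does not register a genome-wide shift. The labels do not say whether the numbers pair libraries. The replicate block gave 27 windows, 0 cytosines and -1.04 points genome-wide. The promoter, gene body, island, feature class and gene list alternatives were not run. Of 54 class alternatives 5 changed sign, among them 0.31 points at 80 to 100% when classed on all calls. At this depth and dispersion simulated cytosines of intermediate level changed by 30 and 40 points were recovered in 0 and 10% of cases. With no extra spread they were recovered in 8 and 34%.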

Other observations

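The tests of level classes and domains in this part were chosen after the data were examined. Unmethylated stretches were defined as runs of at least 5 adjacent 1 kb windows with a pooled level under 15%. There were 330 of them, and together they had a level of 7.34% ± 0.14 (SD, n = 2) with DMSO and 7.22% ± 0.038 with 5-azacytidine, with overlapping groups. The longest covered 35 kb of chromosome 7, from 16308001 to 16343000, at 6.86% ± 0.48 and 6.80% ± 0.18. The next longest, of 28 kb, lay on chromosome 3 from 25929001 to 25957000, and the one after it, of 26 kb, on chromosome 2 from 32662001 to 32688000. Both were chosen by length, and their genes were not analysed here.

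Methylation differed widely between chromosomes in the DMSO libraries. Over all calls below the coverage limit, chromosome 5 had the lowest level, 46.9% ± 0.63, and chromosome 31 the highest, 71.6% ± 0.39. Chromosome W, carried by females in birds, was at 68.5% ± 2.4 and chromosome Z at 50.6% ± 0.45 (SD, n = 2 each). These levels and their order hold for that set of calls: over cytosines with at least 5 calls in all 4 libraries W was the lowest at 43.1% ± 1.4, on 280 cytosines, with chromosome 5 at 47.9%, Z at 58.7% and chromosome 31, again the highest, at 77.3%. Calls per cytosine on W relative to autosomes were 0.353 and 0.488 in DMSO replicates 1 and 2 and 0.541 and 0.331 in 5-azacytidine replicates 1 and 2, and on Z they were 0.711, 0.630, 0.594 and 0.733 in the same order. The relative depth of W and Z thus differed between libraries within each group, and W was higher where Z was lower. This argues against the 2 libraries of a group being repeats of one tissue sample. How many embryos each library holds is not known. On the mitochondrion the reverse strand, which held most of its calls, was read as methylated at 6.09% ± 0.42 with DMSO and 6.06% ± 0.19 with 5-azacytidine. The forward strand, with 3494 to 7305 calls per library, was at 32.4% ± 5.7 and 36.3% ± 0.095, and the groups overlapped on both strands.

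One hypothesis was that methylation was lost in proportion to the level of a window, as dilution through replication without maintenance might give. Relative to its DMSO mean, the level in the 5-azacytidine libraries differed by -0.43% in windows at 0 to 10% (0.77 and -1.63% in replicates 1 and 2), -3.05% in windows at 10 to 20%, -2.34% at 20 to 40%, -1.92% at 40 to 60% (-2.50 and -1.34%), -1.23% at 60 to 80% and -0.54% at 80 to 100% (-0.80 and -0.28%). Without 5-azacytidine replicate 1 the difference in the highest class went from -0.43 to -0.22 points. The order of the classes depended on how they were formed. When windows were classed and read on all calls, the relative differences from the lowest to the highest class were -2.31, -3.72, -3.81, -2.57, -0.91 and 0.37%, and the difference at 20 to 40% went from -0.78 to -1.19 points. The contrast of the last class with that at 40 to 60%, in the classes formed on one strand, had an interval that included 0. The 2 libraries per group leave the hypothesis open.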
